A study of Oryctolagus cuniculus and Mus musculus and Bos taurus with 361 samples.

How the data were processed

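The data are the tables of raw counts that the authors deposited for mouse, pig, cow, rabbit and rhesus embryos, mouse and rabbit embryonic stem cells, and late 2-cell mouse embryos made with the parent protocol. Per the labels, reads were aligned with STAR and counted over genes and repeats with bedtools, with no versions given. How reads with several alignments were counted, and the cow genome build, are not given in the sources. All values were whole numbers and were used as counts. The tables held 76 mouse, 81 pig, 82 cow, 82 rabbit and 19 rhesus embryo libraries, 6 mouse and 5 rabbit stem cell libraries and 4 of the parent protocol, 355 in all. They listed 54838 mouse, 25880 pig, 28943 cow, 23669 rabbit and 32386 rhesus genes, with 1369, 776, 776, 806 and 1243 repeat subfamilies and 92 spike-in RNAs in each embryo table. Symbols existed for 54723 mouse genes and for no genes of the other species, so only mouse genes are named and gene lists are tested in mouse alone.

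Each comparison was tested with the edgeR quasi-likelihood method (edgeR 4.0.16 in R 4.3.3) on counts with TMM normalisation and filterByExpr at a minimum count of 10 and a minimum total of 15. Genes and repeats were fitted together, 2 groups at a time, and spike-ins were left out of the library size, except in the parent protocol table, whose entries carry no identifiers. The rhesus stages shared 1 fit, with the single 4-cell library in the fit but in no contrast. Benjamini-Hochberg adjustment ran over genes and repeats of a comparison at 0.05. The SE of a log2 fold change is its size over the square root of its F statistic. The 5 rabbit stem cell libraries were summed to 3 by culture number. The comparisons, the activation step of each species, the test, the naming rule and 14 alternative settings were chosen before the data were examined.

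Named genes passed the test, had a mean of at least 20 CPM in the higher group and the same sign in at least 90% of pairs of libraries. The largest 12 in each direction were eligible for activation, stem cell and whole-span comparisons and 4 for other steps, and the text gives a selection. For pig, cow, rabbit and rhesus at most 2 identifiers per direction are given, where shown. The same rule for repeats, and the naming of mouse genes over the oocyte to 16-cell span, were set after the data were seen, since the planned rule needed symbols in every species. In all 27 gene lists were written from general knowledge beforehand and repeat families were taken from the tables. Sets with at least 5 members tested were compared with camera (limma 3.58.1) at a preset correlation of 0.01, two-sided, adjusted over the sets of a comparison, and again with an estimated correlation.

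The repeat share, and the log2 ratio of endogenous to spike-in counts, were compared between stages with permutation tests on the difference of means, exact where all splits could be listed and otherwise with 100000 resamplings. The overlap of repeat subfamilies between species used 10000 shufflings of names and one-sided Fisher tests of each pair. Libraries were placed among stages by their correlation with stage means over genes with a mean of at least 5 CPM, their own value left out, and were counted as nearer another stage at a difference over 0.03.

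Alternatives set in advance were DESeq2 size factors in edgeR, no filter, a filter at 10 CPM, DESeq2 1.42.0, all stages in 1 fit (2 groups only in rhesus), the replicate number as a factor, leaving out libraries under 0.25 of their group's median total, leaving out each replicate of small groups, adjusted p under 0.01, and at least 2-fold changes. Chosen after seeing the data were scaling by spike-in counts, leaving out libraries with over 3 times the spike-in share of their group's median, genes without repeats, the 5 rabbit stem cell libraries unsummed, repeat subfamilies in place of genes in the overlap between species, and leaving out libraries nearer another stage. The overlap under spike-in scaling, and the log2 ratio of LTR to MIR and L2 counts in each library, were added last, the limits for the ratio (0.25 and the larger SD of the groups) being set after repeat family shares were known.

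As a test, 2-fold and 4-fold changes were put into 200 genes of simulated counts shaped on the libraries. The 4-fold changes recovered were 79% for early to late 2-cell mouse, 81% for 4-cell to 8-cell cow and 76% for 8-cell to 16-cell rabbit embryos. They were 10% for the added polyadenylation step. In rhesus, as 2 groups without the shared fit, they were 24% from oocyte to zygote and 0% from 2-cell to 8-cell. False calls made up at most 5.37% of calls, untested where most genes change. Raw reads, transcript start sites and samples without a count column were not analysed, nor gene overlap between species, as only mouse had symbols.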

Results

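Single oocytes and preimplantation embryos of mouse, pig, cow, rabbit and rhesus monkey were sequenced one embryo per library, with a protocol that also captures the 5' ends of transcripts, and counts were given for genes and for repeat subfamilies. Stage comparisons ask when each species starts transcribing its genome and which genes and retrotransposons take part. The mouse set (C57BL/6J, natural mating) held 11 oocytes, 11 zygotes, 9 early and 10 late 2-cell, 11 4-cell, 12 8-cell and 12 16-cell embryos. The pig set (fertilised in vitro) held 11 oocytes, 12 zygotes, 11 2-cell, 12 4-cell, 12 day-2, 11 day-3 and 12 morula embryos. The cow set (in vitro) held 11 oocytes, 12 embryos each at the zygote, 2-cell, 4-cell, 8-cell and 16-cell stages, and 11 morulae. The rabbit set (natural mating) held 13 oocytes, 11 zygotes, 11 2-cell, 10 4-cell, 14 8-cell and 12 16-cell embryos and 11 morulae. The rhesus set (in vitro) was small, with 6 oocytes, 4 zygotes, 2 2-cell embryos, 1 4-cell embryo, 3 8-cell and 3 16-cell embryos. There were also 6 libraries of mouse embryonic stem cells with a 2-cell state reporter, and 5 of rabbit ones sorted from feeder cells. A further 4 late 2-cell mouse libraries used the parent protocol, 2 of them with an added polyadenylation step. Total counts per library ran from 604051 to 23110120 with a median of 2186351.

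Fold changes are on the log2 scale, given ± standard error (SE), and levels are counts per 1e+06 (CPM) given as mean ± SD over the libraries of a group. Levels beside fold changes use library sizes after TMM in that comparison, so they differ between comparisons and from the plain CPM of the figure, the MLT1H2 split and the closing parts. Genes and repeats that "rose" or "fell" passed an edgeR test at an adjusted p of 0.05, and the direction is that of their share of the gene and repeat counts. A feature at 0 in every library of a group allows up to 3 counts in each, which came to between 0.183 and 7.07 CPM in the shallowest library of a group, and its fold is given as a lower bound against that floor. Such floors, and the intervals below, cover counting error only. Levels above 0 but under a floor, as for Exoc3l2, have fitted folds that cannot be ranked with these bounds. Mouse positions are on GRCm38.

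Relative to the added spike-in RNA, counts of embryo RNA were lower in zygotes than in oocytes in all 5 species, and lower again at some later steps. The log2 ratio of endogenous to spike-in counts was 6.82 ± 0.881 in mouse oocytes and 5.51 ± 0.536 in zygotes (permutation test, adjusted p = 0.00279). It was lower in late 2-cell than in early 2-cell embryos, 3.97 against 5.25 (exact permutation test, adjusted p = 7.15e-05), and higher at the 8-cell than at the 4-cell stage, 4.74 against 3.87 (permutation test, adjusted p = 0.0151). Cow oocytes had 8.53 and zygotes 7.10, and rabbit oocytes 8.39 and zygotes 7.20 (permutation test, p = 1e-05, the smallest that 100000 resamplings can give, adjusted p = 7.15e-05 in both species). In cow the ratio went from 6.90 at the 4-cell stage to 6.19 at the 8-cell stage, 5.29 at the 16-cell stage and 6.14 in morulae (adjusted p = 0.0202, 0.0151 and 0.0169), and in rabbit from 6.59 at the 4-cell stage to 5.51 at the 8-cell stage (adjusted p = 0.00573), 6.06 at the 16-cell stage and 6.98 in morulae (adjusted p = 0.00573 and 0.0298, all permutation tests). Pig oocytes had 8.17 and zygotes 7.18 (permutation test, adjusted p = 0.00699), 2-cell pig embryos had 6.22 (adjusted p = 0.0151), 4-cell pig embryos 6.36 against 5.26 on day 2 (adjusted p = 0.0256), morulae 7.05 against 6.04 on day 3 (adjusted p = 0.00279), and rhesus oocytes 8.68 against 5.11 in zygotes (exact permutation test, p = 0.00476, adjusted p = 0.0121). All tests were two-sided and adjusted over the 33 comparisons with spike-ins.

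**Figure D1:**
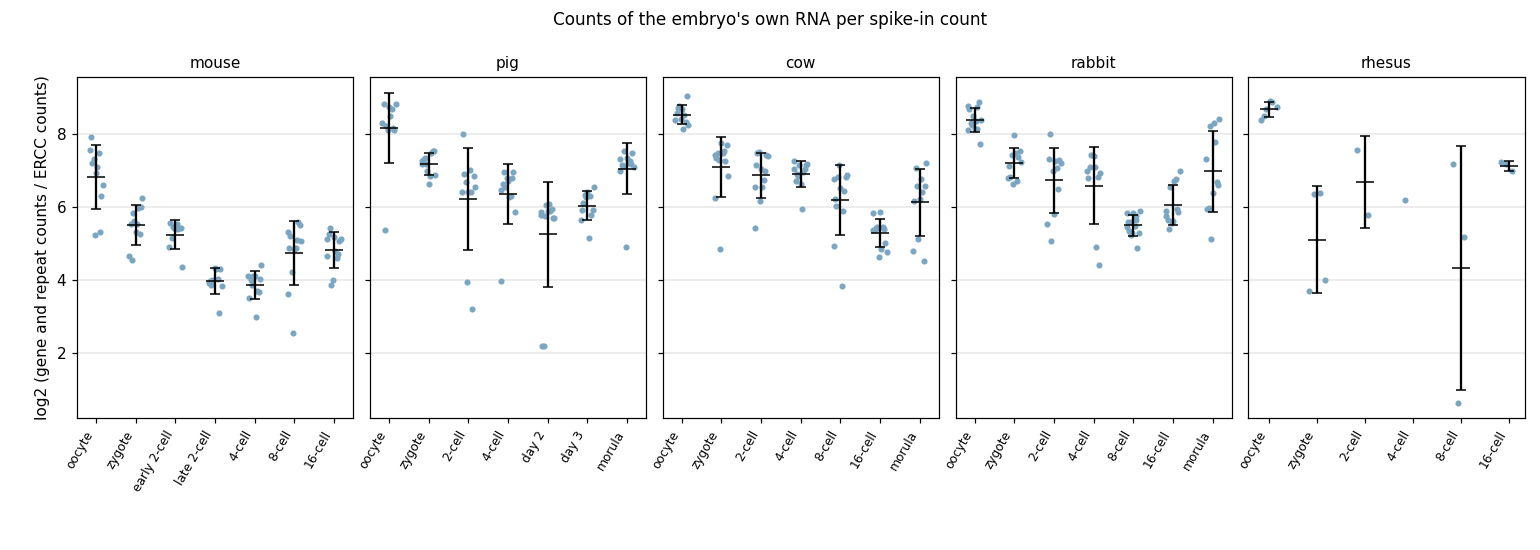
Log2 of endogenous over spike-in counts (vertical axis, no unit) for each library (points) by stage (horizontal axis) and species, with the mean and SD of each stage. Mouse embryos start at a mean of 6.82 in oocytes and reach their lowest mean, 3.87, at the 4-cell stage.

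The share of counts in repeats rose from the zygote to the 2-cell stage in mouse and rabbit. In mouse the repeat share was 18.0% in zygotes, 25.9% in early 2-cell embryos (permutation test, p = 1e-05, again the smallest possible, adjusted p = 0.000165) and 33.7% ± 4.73 in late ones (exact permutation test, adjusted p = 0.00103). It was 28.0% at the 8-cell and 17.7% at the 16-cell stage (permutation test, the same smallest p, adjusted p = 0.000165). In rabbit it was 9.90% in oocytes, 8.29% in zygotes and 11.3% in 2-cell embryos (adjusted p = 0.00891 and 0.00044). It was 12.1%, 9.92% and 7.38% at the 8-cell and 16-cell stages and in morulae (adjusted p = 0.0239 and 0.046, all permutation tests). From zygote to morula the LTR MLT1H held 1.94%, 4.61%, 1.28% (4-cell), 7.8%, 5.87% and 2.68%. The repeat share fell from oocyte to zygote in pig (17.9% to 13.6%) and cow (8.09% to 6.54%, permutation test, adjusted p = 0.000594 for each). In cow it was 5.78% at the 16-cell stage (against oocytes, permutation test, adjusted p = 0.00077). In pig it was 19.5% ± 8.76 on day 3 and 35.6% ± 6.68 in morulae (permutation test, adjusted p = 0.00099). Rhesus zygotes had 18.3% ± 2.80 against 45.4% ± 1.71 in oocytes (exact permutation test, p = 0.00476, adjusted p = 0.0157), and 16-cell embryos 35.9% (exact permutation test against oocytes, p = 0.0119, adjusted p = 0.0327). For steps from rhesus zygote to 16-cell embryo groups are too small for a test to reach 0.05 (smallest exact p 0.0667 to 0.1).

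**Figure D2:**
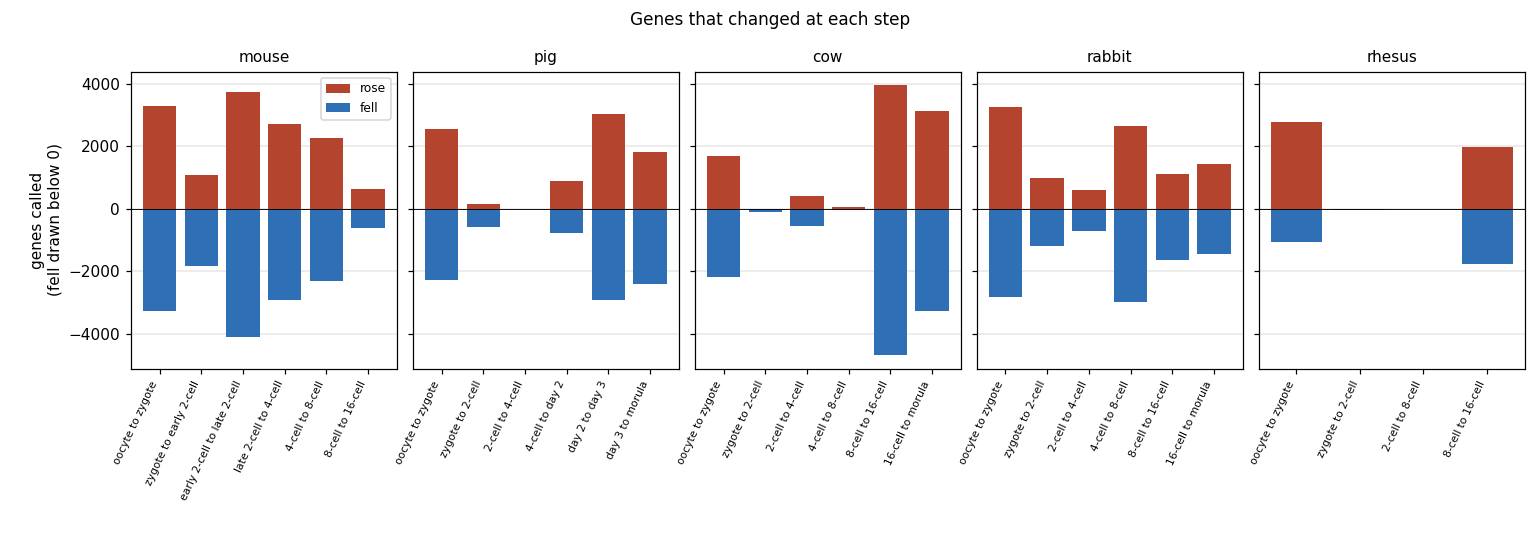
Number of genes that rose (above 0) and fell (below 0) at each step (horizontal axis) in each species, from the edgeR test at an adjusted p of 0.05. Among bars above 0 the tallest mark 3735 genes up at the early to late 2-cell step in mouse and 3960 up at the 8-cell to 16-cell step in cow.

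From mouse oocyte to zygote, messages for ribosomal proteins and for nuclear-encoded respiratory chain subunits fell, while mitochondrially encoded messages and replication-dependent histones rose in share. Rps19 (ENSMUSG00000040952.16, chromosome 7, 24884371 to 24889806), a small-subunit ribosomal protein, went from 194.7 ± 30.25 to 2.07 ± 1.06 CPM, a change of −6.49 ± 0.187, Rps27 changed by −6.48 ± 0.293 and Rpsa by −6.19 ± 0.286. Ccnd2, a cyclin of the G1 phase, changed by −6.29 ± 0.61. Hist1h4n rose by 4.34 ± 0.414 and the mitochondrial serine tRNA mt-Ts2 by 4.43 ± 0.32. So did the miRNA genes Gm24270 (5.13 ± 0.336) and Gm23935 (5.08 ± 0.285). Among ribosomal protein genes 81 of 86 fell, 1 rose and 4 did not pass (82 adjusted over the list alone, below "by list alone"), with a median of −2.82 and −4.36 under spike-in scaling. The riser was Rps27l (1.17 ± 0.136). The camera set test gave this list an adjusted p of 1.38e-28, or 0.278 with an estimated correlation. Of 80 nuclear respiratory chain genes 74 fell and 4 rose (78 by list alone), among them Ndufa9 (−4.74 ± 0.299), Cox7c (−4.66 ± 0.159) and Uqcr11 (−4.62 ± 0.323), with adjusted p = 4.64e-22, or 0.278 with an estimated correlation. All 12 mitochondrially encoded messages tested rose (12 by list alone), mt-Atp8 by 2.34 ± 0.232 and mt-Cytb by 2.17 ± 0.243 (adjusted p = 4.92e-06, or 0.413 with an estimated correlation). Of 18 histone genes 13 rose and 3 fell (16 by list alone), with Hist1h4c at 3.84 ± 0.247 and Hist1h2bc at −2.88 ± 0.198 (adjusted p = 0.00417, or 0.448 with an estimated correlation). Under spike-in scaling the medians of these lists went from 2.02 and 1.71 to 0.488 and 0.284, with 3 mitochondrial messages up and none down and 7 histone genes up and 6 down. Oocyte factors divided, 20 of 34 falling and 10 rising (31 by list alone). The zona pellucida genes Zp3 and Zp2 changed by −4.21 ± 0.313 and −2.96 ± 0.179, and the kinase gene Mos by −3.94 ± 0.319. Btg4, an adaptor of mRNA deadenylation, rose by 0.98 ± 0.138. Proteasome subunits fell in 22 of 33 cases and rose in 5 (28 by list alone), with Psmb5 at −3.98 ± 0.271, and 9 of 12 RNA polymerase II subunits fell and 1 rose (10 by list alone), with Polr2l at −2.78 ± 0.284 (adjusted p = 0.000419 and 0.00417, or 0.448 and 0.282 with an estimated correlation). Of 3 sperm markers tested, Akap4 rose by 0.64 ± 0.172 and Prm2 fell by 0.83 ± 0.299. Among repeats, 7SK RNA rose by 4.25 ± 0.544 and LSU-rRNA_Hsa by 3.04 ± 0.221, and the LTR RLTR47 fell by 3.52 ± 0.341. In all, 3285 genes rose and 3271 fell of 10293 tested, with 103 repeats up and 100 down of 574. Scaling by spike-ins moved the median gene by −1.49 and gave 29 genes up and 9003 down, with 5 repeats up and 527 down.

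From mouse zygote to early 2-cell embryo, the first genes and repeats of the 2-cell programme appeared and oocyte messages fell. Gm44660 and Gm33466 were at 0 in all 11 zygotes and at 28.1 ± 14.4 and 20.2 ± 18.8 CPM in the 9 early 2-cell embryos, at least 8.12-fold and 5.82-fold higher. Zfp352 (ENSMUSG00000070902.5, chromosome 4, 90218820 to 90225702), a zinc finger gene known from 2-cell embryos, rose by 7.57 ± 0.53, and the deubiquitinase gene Usp17lc by 5.48 ± 0.486. H1foo (ENSMUSG00000042279.13, chromosome 6, 115944938 to 115950236), the oocyte linker histone, went from 3017 ± 1321 to 320.6 ± 120 CPM, a change of −3.23 ± 0.277, Rpl13 changed by −3.07 ± 0.252 and Ints9 by −2.997 ± 0.234. The endogenous retrovirus MERVL rose by 5.74 ± 0.448 and its LTR MT2_Mm by 3.32 ± 0.265. The LINE segment L1MdA_III_orf2 rose by 3.58 ± 0.447 and the major satellite GSAT_MM by 3.46 ± 0.602. IAPLTR2a fell by 1.84 ± 0.304 and RLTR10 by 1.48 ± 0.232. Of 15 genome activation markers 7 rose and 1 fell (10 by list alone), Duxf3 by 5.04 ± 0.527, Zscan4d by 3.50 ± 0.635 and Tcstv1 by 1.58 ± 0.388, with a list median of 0.36 that turned to −0.09 under spike-in scaling (adjusted p = 0.000151, or 0.0705 with an estimated correlation). Oocyte factors fell in 17 of 34 cases and rose in 2 (21 by list alone), with Gdf9 at −1.67 ± 0.194 (adjusted p = 0.000127, or 0.0467 with an estimated correlation). Ribosome biogenesis genes fell in 20 of 38 cases and rose in 3 (28 by list alone), Mybbp1a by −2.04 ± 0.268 and Nop14 by −1.85 ± 0.174 (adjusted p = 7.77e-05, or 0.0467 with an estimated correlation). The L1 family had 127 of 160 subfamilies up and 1 down (134 by list alone), with a median of 0.87 and 0.47 under spike-in scaling (adjusted p = 3.35e-31, or 0.0467 with an estimated correlation). ERVL-MaLR subfamilies rose in 39 of 63 cases and none fell (44 by list alone, adjusted p = 3.7e-12, or 0.148 with an estimated correlation). There were 1088 genes up and 1845 down of 9648, and 312 repeats up and 14 down of 623. Spike-in scaling moved the median gene by −0.42 and gave 44 up and 2145 down, with 61 repeats up and 21 down.

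Between the early and late 2-cell stage, the mouse activation step set in advance, embryonic genes rose from near 0 and oocyte messages fell. Exoc3l2 (ENSMUSG00000011263.16, chromosome 7, 19463331 to 19496762), an exocyst-like gene, went from 0.0292 (floor 3.14) to 902.4 ± 286.4 CPM (13.12 ± 0.405). Folr1, a folate receptor, rose by 10.56 ± 0.401, the homeobox gene Obox8 by 9.83 ± 0.497, the transcription factor gene Gata1 by 9.29 ± 0.669 and Npl, a sialic acid lyase, by 9.27 ± 0.506. The growth factor gene Fgf4 (chromosome 7, 144847367 to 144865243) was at 0 in all 9 early embryos and at 70.2 ± 33.8 CPM in the 10 late ones, at least 22.4-fold higher, and Gm43421, Gm16145 and Gm37726, also at 0 in early embryos, were at least 18.7-fold, 13.3-fold and 12.1-fold higher. Rgs2 (ENSMUSG00000026360.9, chromosome 1, 143999338 to 144004161), a regulator of G-protein signalling, went from 1336 ± 223.1 to 18.0 ± 7.13 CPM, a change of −6.21 ± 0.213. Cldn8, a tight junction claudin, changed by −5.62 ± 0.409, the caspase gene Casp8 by −5.52 ± 0.428, the early activator Duxf3 by −5.36 ± 0.547, Sox8 by −5.15 ± 0.438, Pstpip1 by −5.13 ± 0.385, Pja1 by −5.09 ± 0.297, Zfp58 by −5.06 ± 0.37 and Oas1h by −4.95 ± 0.241.

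Repeats moved with these mouse genes. The LTR ORR1A0 went from 267.9 ± 168.3 to 10150 ± 4480 CPM (5.24 ± 0.377), ORR1A1 rose by 4.41 ± 0.239, GSAT_MM by 4.37 ± 0.482, MERVL by 3.84 ± 0.384 to 20380 ± 7301 CPM and MT2B by 3.74 ± 0.22. MTB_Mm fell by 2.52 ± 0.2, RodERV21 by 2.43 ± 0.167 and Eutr18 by 3.82 ± 0.276. Of 33 oocyte factors 31 fell and 1 rose (33 by list alone), Bcl2l10 by −3.60 ± 0.312 and Ooep by −3.39 ± 0.286, with a list adjusted p = 2.98e-07, or 0.547 with an estimated correlation. Ribosomal protein genes rose in 83 of 85 cases and 1, Rps27l, fell (84 by list alone), with a median of 3.54 and of 2.04 under spike-in scaling, Rps27 at 7.75 ± 0.428 and Rpsa at 7.17 ± 0.32 (adjusted p = 6.73e-22, or 0.547 with an estimated correlation). Ribosome biogenesis genes rose in 37 of 42 cases and fell in 2 (39 by list alone), Nop2 by 5.75 ± 0.274 and Rrs1 by 5.72 ± 0.372, while Bms1 changed by −2.21 ± 0.229 (adjusted p = 5.71e-07, or 0.547 with an estimated correlation). Genome activation markers split into 16 that rose and 11 that fell of 32 (27 by list alone, adjusted p = 0.312), with Obox6 at 8.66 ± 0.482, Trim43a at 8.29 ± 0.368, Pramel7 at 7.34 ± 0.556 and Obox1 at −4.06 ± 0.273. Pluripotency factors rose in 10 of 15 cases and fell in 2 (12 by list alone, adjusted p = 0.078), L1td1 by 8.04 ± 0.462 and Dppa4 by 5.62 ± 0.342, while Pou5f1 changed by −2.20 ± 0.219. Of 182 L1 subfamilies 149 rose and 6 fell (156 by list alone), but their median of 1.21 became −0.23 under spike-in scaling (adjusted p = 3.2e-06, or 0.903 with an estimated correlation). All 17 Alu-type B1 subfamilies rose (17 by list alone, adjusted p = 0.000134, or 0.573 with an estimated correlation). The step had 3735 genes up and 4104 down of 9774, and 392 repeats up and 111 down of 667. Under spike-in scaling the median gene moved by −1.59 with 1812 up and 6601 down, with 53 repeats up and 323 down.

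At the late 2-cell to 4-cell step of the mouse, oocyte factors declined further while ribosomal protein and proteasome genes rose. Tdgf1 (ENSMUSG00000032494.12, chromosome 9, 110939603 to 110946158), a Nodal co-receptor, rose by 7.61 ± 0.836, Bhmt, a methyltransferase of homocysteine, by 6.98 ± 0.667, the transcription factor gene Hand1 by 6.37 ± 0.771 and Sfn, the 14-3-3 sigma protein, by 6.25 ± 0.556. The neighbouring Tcl1b4, Tcl1b3 and Tcl1b1 genes of chromosome 12 changed by −5.67 ± 0.547, −5.58 ± 0.533 and −5.55 ± 0.447. Of 30 oocyte factors 29 fell and 1 rose (30 by list alone), Zbed3 by −5.12 ± 0.449 and Bcl2l10 by −4.60 ± 0.381, while Khdc3 rose by 1.78 ± 0.403 (adjusted p = 4.24e-11, or 0.272 with an estimated correlation). Proteasome subunits rose in 31 of 34 cases and none fell (32 by list alone), Psma7 by 4.04 ± 0.252 and Psmb3 by 3.40 ± 0.433 (adjusted p = 1.55e-10, or 0.272 with an estimated correlation). Nuclear respiratory chain genes rose in 64 of 78 cases and fell in 4 (69 by list alone), Ndufa3 by 3.98 ± 0.401, and ribosomal protein genes rose in 85 of 87 cases and fell in 1 (86 by list alone), with adjusted p = 8.39e-13 and 9.11e-25, or 0.272 and 0.352 with an estimated correlation. Zscan4b changed by −4.76 ± 0.532 and Usp17lc by −3.93 ± 0.528. RLTR45-int rose by 3.87 ± 0.302 and ERVB4_2-I_MM by 3.64 ± 0.359, and MER73 fell by 3.92 ± 0.39 and BGLII by 2.41 ± 0.209. There were 2705 genes up and 2916 down of 8837 and 51 repeats up and 123 down of 682, and under spike-in scaling (median −0.16) 2064 up and 2977 down, with 31 repeats up and 123 down.

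From the 4-cell to the 8-cell stage in mouse, cell junction and pluripotency genes rose. Tspan1 (ENSMUSG00000028699.9, chromosome 4, 116161869 to 116167601), a tetraspanin, rose by 7.66 ± 0.428, Crip2 by 5.84 ± 0.39 and the desmosome gene Perp by 5.42 ± 0.483. Usp17lb changed by −5.57 ± 0.661, Tnfaip8l2 by −4.602 ± 0.435 and Slain1 by −4.26 ± 0.474. Of 21 junction and polarity genes 14 rose and 2 fell (16 by list alone), the water channel gene Aqp3 by 4.17 ± 0.55, Cldn4 by 4.07 ± 0.581 and E-cadherin, Cdh1, by 2.61 ± 0.296, while Itga6 changed by −1.231 ± 0.259 (adjusted p = 0.000266, or 0.449 with an estimated correlation). Pluripotency factors rose in 12 of 21 cases and fell in 1 (13 by list alone), Tfcp2l1 by 4.68 ± 0.475 and Pou5f1 by 3.34 ± 0.376 (adjusted p = 0.00676, or 0.574 with an estimated correlation). Gata6 of the primitive endoderm rose by 4.11 ± 0.367. Of 21 oocyte factors 20 fell and 1 rose (21 by list alone), Omt2b by −3.63 ± 0.347 and Kit by −3.16 ± 0.31 (adjusted p = 1.89e-09, or 0.371 with an estimated correlation). The oocyte LTR MTA_Mm fell by 3.44 ± 0.274 and MERVL by 3.29 ± 0.249 to 651.8 ± 332.5 CPM. In total 2253 genes rose and 2315 fell of 8373, with 62 repeats each way of 654. The median gene was 0.95 higher under spike-in scaling, which gave 4481 up and 322 down, with 381 repeats up and 10 down.

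At the 8-cell to 16-cell step trophectoderm keratins rose in mouse embryos. Krt8 (ENSMUSG00000049382.10, chromosome 15, 101996698 to 102004482) went from 6.53 ± 5.03 to 63.6 ± 40.9 CPM (3.37 ± 0.421), and the syndecan gene Sdc4 rose by 3.08 ± 0.477, Krt18 by 2.57 ± 0.361 and Ass1, an enzyme of arginine synthesis, by 2.45 ± 0.42. Trophectoderm markers rose in 6 of 12 cases and none fell (9 by list alone, adjusted p = 5.35e-05, or 0.00557 with an estimated correlation), with Dab2 at 1.95 ± 0.313 and Gata3 at 1.36 ± 0.312. Cdx2 was at 7.77 CPM before and 18.2 CPM after (1.14 ± 0.459, adjusted p = 0.0905). The RNase P RNA gene Rpph1 fell by 4.05 ± 0.519, Ccnb1ip1 by 2.36 ± 0.324 and mt-Ts2 by 2.19 ± 0.246. The SINEs B1_Mus1 and B2_Mm1t fell by 1.72 ± 0.292 and 1.49 ± 0.256, and MER89 rose by 1.80 ± 0.284. This step had 642 genes up and 604 down of 8211 and 12 repeats up and 46 down of 648. Spike-in scaling, with a median of 0.13, left 83 genes up and 32 down, with 3 repeats up and 3 down.

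Over the whole span from mouse oocyte to 16-cell embryo, most oocyte factors fell and pluripotency factors rose. The homeobox gene Crxos (ENSMUSG00000074365.13, chromosome 7, 15882617 to 15904020) was at 0 in all 11 oocytes and at 1429 ± 422.5 CPM in 12 16-cell embryos, at least 1030-fold higher. By the same measure Bhmt was at least 658-fold, Gm12617 375-fold, Folr1 369-fold, Pramel7 287-fold, Pramel4 245-fold, Pramel6 196-fold and the creatine transporter gene Slc6a8 191-fold higher. Calcoco2, an autophagy receptor, rose by 14.44 ± 0.324, Trim43a by 13.80 ± 0.287, Timd2 by 13.77 ± 0.326 and Trim43b by 13.23 ± 0.297. Fbxw22, at 312.7 ± 72.7 CPM in oocytes, was at 0 in all 12 16-cell embryos, at least 75.6-fold lower, and A730082K24Rik was at least 47.7-fold lower. The maternal-effect gene Zar1 (ENSMUSG00000063935.3, chromosome 5, 72576806 to 72581254) changed by −11.87 ± 0.3, H1foo by −11.66 ± 0.271, Fbxw18 by −12.10 ± 0.253, Gm813 by −11.95 ± 0.265, E330017A01Rik by −12.62 ± 0.27 and Cmya5 by −11.79 ± 0.267. Of 33 oocyte factors 32 fell (32 by list alone, adjusted p = 3.08e-11, or 0.00986 with an estimated correlation), and Khdc3 stood at −0.17 ± 0.205. Pluripotency factors rose in 19 of 20 cases (19 by list alone), Klf5 by 10.87 ± 0.345, Tdgf1 by 10.92 ± 0.306 and Nanog by 4.39 ± 0.451 (adjusted p = 1.16e-06, or 0.00986 with an estimated correlation). Their median was 4.90, or 4.29 with the 2 members at 0 in oocytes set to their bound. Trophectoderm markers rose in 10 of 13 cases and fell in 1 (11 by list alone, adjusted p = 0.00926, or 0.115 with an estimated correlation). Ribosomal protein genes rose in 87 of 88 cases and 1 fell (88 by list alone, median 2.92, and 0.44 under spike-in scaling, adjusted p = 1.91e-20, or 0.44 with an estimated correlation). The LTR element RLTR45-int rose by 7.35 ± 0.291, L1MdTf_II_orf2 by 7.03 ± 0.443 and MT2B by 5.37 ± 0.197. Eutr18 fell by 7.31 ± 0.264, MTA_Mm by 6.85 ± 0.223 and MT-int by 5.04 ± 0.127. L1 subfamilies rose in 168 of 185 cases and fell in 9 (177 by list alone), a median of 2.19 that became −0.10 under spike-in scaling (adjusted p = 1.48e-10, or 0.732 with an estimated correlation). The span had 4528 genes up and 5536 down of 11292 and 450 repeats up and 145 down of 695, and with the median gene at −2.75 under spike-in scaling 1463 up and 8492 down, with 90 repeats up and 400 down.

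**Figure D3:**
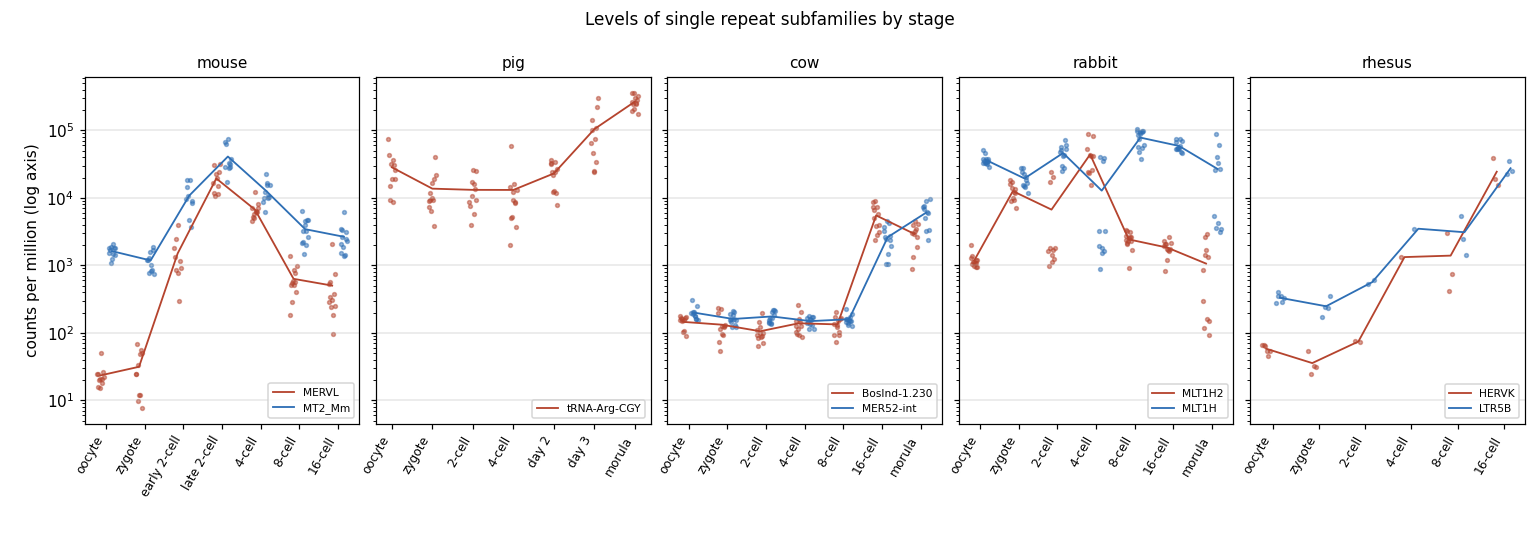
Level of selected repeat subfamilies (vertical axis, CPM, log scale) in each library (points) by stage (horizontal axis) and species, with a line through the stage means. MERVL in mouse peaks at 19360 CPM in late 2-cell embryos, and HERVK in rhesus reaches 24360 CPM at the 16-cell stage.

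Pig genes carried no names, so repeats are described by name and genes by count. From pig oocyte to zygote repeats fell, with changes of −1.90 ± 0.208 in L1MEg1_5end, −2.04 ± 0.257 in MamGypsy2-I and, in LTR65, −1.815 ± 0.247. In contrast LSU-rRNA_Hsa rose by 1.94 ± 0.429 and the DNA transposon Looper by 1.44 ± 0.315. Of 63 ERVL subfamilies 40 fell and 1 rose (41 by list alone), and of 42 ERVL-MaLR subfamilies 24 fell (26 by list alone), with adjusted p = 0.000368 and 0.000224, or 0.591 with an estimated correlation for each. Genes divided into 2560 up and 2264 down of 8926, with 22 repeats up and 234 down of 482. Under spike-in scaling (median −0.94) 8 genes rose and 5511 fell, with 2 repeats up and 445 down. From zygote to 2-cell embryo 169 genes rose and 567 fell of 8508, with 7 repeats up, MLT1C by 0.55 ± 0.137, and 1 down, L1M8_5end by 0.55 ± 0.133, of 469. Spike-in scaling (median −0.57) turned MLT1C to −0.02 and gave 1 gene up and 715 down, with 0 repeats up and 2 down. The 2-cell to 4-cell step had 5 genes up and 4 down of 8149 by edgeR (1030 at an unadjusted p under 0.05), with 0 repeats up and 0 down of 471, and 131 genes by DESeq2. With spike-in scaling (median −0.16) 1 gene rose and 0 fell.

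For pig the activation step set in advance was 4-cell to day 2, and more genes passed from day 2 to day 3. At the 4-cell to day-2 step ENSSSCG00000034113 rose by 5.95 ± 0.919 to 606.2 ± 635.4 CPM and ENSSSCG00000002968 by 5.00 ± 0.838. ENSSSCG00000004766 and ENSSSCG00000037241 changed by −1.93 ± 0.256 and −1.92 ± 0.257. LTR109A2 rose by 1.93 ± 0.399, MER96B by 1.36 ± 0.248 and L1M2_orf2 by 1.21 ± 0.237, and MER21C fell by 0.65 ± 0.13. L1 subfamilies rose in 41 of 81 cases and none fell (53 by list alone), a median of 0.47 that became −0.44 under spike-in scaling (adjusted p = 5.65e-12, or 0.712 with an estimated correlation). Genes numbered 897 up and 774 down of 8091 and repeats 88 up and 8 down of 483, and under spike-in scaling (median −0.91) 112 genes rose and 2294 fell, with 0 repeats up and 46 down. From day 2 to day 3 counts at tRNA-derived repeats rose, tRNA-Arg-CGY by 2.98 ± 0.528 from 20270 ± 10210 to 160400 ± 198500 CPM, tRNA-Arg-CGA by 2.70 ± 0.457 and tRNA-Ile-ATT by 2.41 ± 0.422. In that family 12 of 15 members rose and none fell (12 by list alone, adjusted p = 0.00936, or 0.712 with an estimated correlation). MER67D fell by 2.11 ± 0.408, MLT1E by 2.02 ± 0.275 and LTR65 by 1.92 ± 0.261. In all 30 of 43 ERVL-MaLR subfamilies fell and 3 rose (33 by list alone, adjusted p = 9.55e-05, or 0.712 with an estimated correlation). The step had 3041 genes up and 2905 down of 8294 and 87 repeats up and 172 down of 472. Spike-in scaling (median −0.11) gave 2211 up and 1772 down, with 24 repeats up and 71 down. From day 3 to morula Charlie15b rose by 2.73 ± 0.376, tRNA-Ser-TCY by 1.83 ± 0.441 and tRNA-Ile-ATT by 1.77 ± 0.403. LTR53B fell by 3.29 ± 0.566 and LTR45 by 2.71 ± 0.463. Here 13 of 19 tRNA-derived members were up and 1 down (14 by list alone, adjusted p = 0.000655, or 0.967 with an estimated correlation). Here 1830 genes rose and 2390 fell of 8257, with 107 repeats up and 77 down of 473, and spike-in scaling (median 0.50) gave 2898 up and 843 down, with 222 repeats up and 16 down.

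Over the span from pig oocyte to day 3 the repeats L1M3a_5end, tRNA-Ser-TCY and L1MA10_3end rose by 3.88 ± 0.378, 3.57 ± 0.599 and 2.53 ± 0.267, the last of them turning to −0.22 under spike-in scaling. LTR65 fell by 4.14 ± 0.267, 7SK by 3.52 ± 0.577 and MLT1E1 by 3.19 ± 0.314. Of 80 L1 subfamilies 52 rose and 14 fell (67 by list alone), with a median of 0.82 that became −1.93 under spike-in scaling (adjusted p = 0.000692, or 0.932 with an estimated correlation). Of 8828 genes 3120 rose and 2827 fell, and of 483 repeats 148 rose and 181 fell. The median gene moved by −2.71 under spike-in scaling, which gave 244 up and 7610 down, with 1 repeat up and 457 down. One day-3 library, replicate 1, had a gene profile nearer to 4-cell embryos than to its own stage (r = 0.886 against 0.427). Without it 3245 genes rose and 3260 fell from day 2 to day 3, 2065 and 2455 from day 3 to morula, and 3428 and 3310 over the span.

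Cow genes carried no names either. From cow oocyte to zygote U1 RNA fell by 2.13 ± 0.329, the DNA transposon Cheshire by 2.01 ± 0.292, MER110-int by 1.74 ± 0.241 and LTR102_Mam by 1.73 ± 0.268. At this step 17 of 33 ERVL-MaLR subfamilies fell (22 by list alone, adjusted p = 0.000198, or 0.449 with an estimated correlation). There were 1683 genes up and 2178 down of 11113, 6 repeats up and 147 down of 450, and under spike-in scaling (median −1.19) 7 genes up and 9811 down, with 0 repeats up and 443 down. Fewer genes passed at the 3 following steps. From zygote to 2-cell embryo 7 genes rose and 117 fell of 10603, and LTR53B was among the 3 of 415 repeats that fell, by 0.79 ± 0.172. From the 2-cell to the 4-cell stage 423 genes rose and 558 fell of 10790, with 4 repeats up and 2 down of 421, MLT1H2 by −0.51 ± 0.131. From the 4-cell to the 8-cell stage 50 genes rose and 38 fell of 10975, and 1 of 443 repeats rose. At that step 0 of 80 L1 subfamilies passed over all features but 22 did when by list alone, with a median of 0.33 that became −0.30 under spike-in scaling (adjusted p = 2.12e-13, or 0.386 with an estimated correlation). Spike-in scaling moved the median gene by −0.20, 0.04 and −0.60 at these 3 steps and gave 0 up and 66 down, 5 up and 107 down, and 54 up and 449 down.

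Large changes in cow came between the 8-cell and the 16-cell stage, the activation step set in advance. XM_005194802.3 was at 0 in all 12 8-cell embryos and at 2511 ± 1007 CPM in 16-cell embryos, at least 2260-fold higher, NM_001206532.1 rose by 15.48 ± 0.573. NM_001075685.1 and XM_010819892.2 changed by −3.95 ± 0.358 and −3.87 ± 0.473. The small RNA family U17 rose by 7.91 ± 0.526, as did some LTR elements, BosInd-1.230 from 102.2 ± 30.4 to 7202 ± 2850 CPM (6.14 ± 0.295), MER83B-int by 6.17 ± 0.409 and MER52-int by 4.81 ± 0.256. The DNA transposons MamRep137, MER104, Tigger6b and Charlie31a rose by 4.38 ± 0.29, 3.55 ± 0.302, 3.45 ± 0.312 and 2.93 ± 0.248. UCON80_AMi changed by −2.95 ± 0.291, LTR52 by −2.57 ± 0.202, LTR45 by −2.45 ± 0.234, MER76 by −2.13 ± 0.212, LTR75 by −1.82 ± 0.273 and L1MCa_5end by −1.231 ± 0.162. Of 82 L1 subfamilies 64 rose and 8 fell (73 by list alone), but the median of 1.18 became −0.57 under spike-in scaling, and of 61 hAT-Charlie subfamilies 40 rose and 7 fell (47 by list alone), a median of 0.78 that became −0.995 (adjusted p = 4.34e-05 and 0.00996, or 0.904 with an estimated correlation for each). The step had 3960 genes up and 4677 down of 11279 and 241 repeats up and 83 down of 479, against 1397 genes up and 7964 down with 13 repeats up and 313 down under spike-in scaling (median −2.07). From 16-cell to morula 5S RNA rose by 2.48 ± 0.321 and MER70-int by 2.35 ± 0.336, while the ERVL repeats LTR16D2, LTR33C and LTR16A fell by 4.50 ± 0.434, 3.20 ± 0.519 and 3.13 ± 0.267. Genes counted 3114 up and 3257 down of 9447 and repeats 41 up and 94 down of 430, and spike-in scaling (median 0.86) gave 4395 up and 1275 down, with 177 repeats up and 17 down. From cow oocyte to 16-cell embryo MER83B-int rose by 6.82 ± 0.422 and BosInd-1.230 by 5.84 ± 0.302, and LTR52 and LTR45 fell by 3.91 ± 0.225 and 3.49 ± 0.256. In all 3848 genes rose and 4479 fell of 11085, with 185 repeats up and 139 down of 467. The spike-in scaled median was −4.00, with 480 genes up and 10130 down, with 5 repeats up and 458 down.

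Rabbit genes, too, had no names. From rabbit oocyte to zygote the LTR MLT1H2 rose by 3.12 ± 0.189, from 1316 ± 417.5 to 11450 ± 3832 CPM, and Plat_L3 by 2.08 ± 0.259. L1MB4_5end fell by 2.98 ± 0.273 and LTR77 by 2.92 ± 0.158. Of 45 ERVL-MaLR subfamilies 33 fell and 2 rose (35 by list alone, adjusted p = 7e-06, or 0.989 with an estimated correlation). There were 3258 genes up and 2808 down of 8681 and 135 repeats up and 137 down of 426, and under spike-in scaling (median −0.83) 421 genes up and 5129 down, with 16 repeats up and 266 down. From zygote to 2-cell embryo LTR16A rose by 1.49 ± 0.138, MER121 by 1.62 ± 0.346 and 5S RNA by 1.52 ± 0.294. X34_DNA fell by 2.08 ± 0.25 and Charlie25 by 1.52 ± 0.292. ERV3 subfamilies rose in 18 of 52 cases and fell in 2 (24 by list alone), a median of 0.49 that became −0.01 under spike-in scaling (adjusted p = 7.2e-05, or 0.841 with an estimated correlation). Counts were 979 genes up and 1177 down of 8863 and 104 repeats up and 14 down of 458, or 62 genes up and 874 down with 2 repeats up and 16 down under spike-in scaling (median −0.36). From the 2-cell to the 4-cell stage MLT1H2 rose by 2.84 ± 0.619 and UCON9 by 2.31 ± 0.607, and L1M4a1_5end fell by 1.36 ± 0.291. MLT1H2 split the 2-cell embryos, with 8 at 993 to 1814 CPM and 3 at 17060 to 24258 CPM. L1 subfamilies fell in 16 of 87 cases and rose in 2 (19 by list alone, adjusted p = 2.94e-07, or 0.946 with an estimated correlation). The step had 602 genes up and 714 down of 8585 and 19 repeats up and 42 down of 439, and with spike-in scaling (median −0.10) 20 genes up and 199 down, with 2 repeats up and 6 down.

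The largest change between cleavage stages in rabbit came from the 4-cell to the 8-cell stage, 1 step before the 8-cell to 16-cell step set in advance as activation. The retrovirus ERVL went from 5.76 ± 3.17 to 400.6 ± 383.5 CPM (6.12 ± 0.507), tRNA-Arg-CGY rose by 5.90 ± 0.589, MER31-int by 4.37 ± 0.346 and LTR16D by 3.72 ± 0.267. MLT1H2 fell by 3.53 ± 0.284 and LTR67B by 2.66 ± 0.223. Of 88 L1 subfamilies 69 rose and 4 fell (73 by list alone), a median of 1 that became −0.80 under spike-in scaling (adjusted p = 2.6e-07, or 0.861 with an estimated correlation). Here 2647 genes rose and 2974 fell of 8009, with 163 repeats up and 81 down of 397, and spike-in scaling (median −2.12) gave 751 genes up and 6106 down, with 11 repeats up and 304 down. From the 8-cell to the 16-cell stage ENSOCUG00000010551 and ENSOCUG00000008164 rose by 3.10 ± 0.676 and 2.98 ± 0.537. ENSOCUG00000005333 and ENSOCUG00000001792 changed by −2.78 ± 0.449 and −2.65 ± 0.405. LTR37-int rose by 1.41 ± 0.288, and FordPrefect fell by 2.96 ± 0.466, MER73 by 1.67 ± 0.293, LTR33A_v by 1.05 ± 0.193 and MLT1K by 0.99 ± 0.187. L1 subfamilies rose in 17 of 89 cases and fell in 1 (10 by list alone, adjusted p = 0.00288, or 0.95 with an estimated correlation). This step had 1127 genes up and 1628 down of 6464 and 43 repeats up and 46 down of 358, or 2471 genes up and 699 down with 179 repeats up and 14 down under spike-in scaling (median 0.45). From 16-cell to morula ERVL rose by 1.33 ± 0.238, MLT2B4 by 1.82 ± 0.341 and L1MEg_5end by 1.297 ± 0.225. LTR52 fell by 1.78 ± 0.426 and Charlie16 by 1.37 ± 0.234. L1 subfamilies rose in 71 of 90 cases and fell in 1 (74 by list alone, adjusted p = 1.3e-14, or 0.307 with an estimated correlation). There were 1425 genes up and 1461 down of 6123, 181 repeats up and 13 down of 370, and with spike-in scaling (median 0.90) 3044 genes up and 326 down, with 304 repeats up and 3 down.

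From rabbit oocyte to 16-cell embryo tRNA-Arg-CGY rose by 7.51 ± 0.486, the Gypsy-type LTR85b by 5.19 ± 0.438, U1 RNA by 5.15 ± 0.341 and MER31-int by 4.73 ± 0.186. MER54A fell by 4.31 ± 0.273, MLT2B5 by 4.17 ± 0.19 and MLT1D by 2.67 ± 0.143. Among 88 L1 subfamilies 76 rose and 6 fell (83 by list alone), a median of 1.52 that became −1.43 under spike-in scaling (adjusted p = 2.31e-09, or 0.742 with an estimated correlation). In all 3102 genes rose and 3704 fell of 8121, with 208 repeats up and 113 down of 396, and spike-in scaling (median −3.24) gave 445 genes up and 7109 down, with 13 repeats up and 351 down. The rabbit libraries 2-cell 9 and 12, 8-cell 14 and 15, 16-cell 6 and morula 12 had gene profiles nearer to another stage than to their own. Without them the gene counts up and down were 843 and 1002, 857 and 961, 2526 and 2923, 1471 and 1921, 1503 and 1550 over the steps from zygote to morula, and 3149 and 3838 over the span, and the repeats that passed from the 2-cell to the 4-cell stage numbered 104 in place of 61.

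Rhesus repeats were lower in zygotes than oocytes and HERVK retroviruses rose by the 16-cell stage. Stages held few embryos, and zygotes 1 and 4 were nearer another stage. From rhesus oocyte to zygote LTR23 went from 1928 ± 305.8 to 7.91 ± 5.29 CPM (−7.90 ± 0.524), and LTR47B2 changed by −7.96 ± 0.681, MER50C by −5.50 ± 0.833 and MER92C by −5.30 ± 0.549. UCON97 rose by 11.30 ± 0.943, and D20S16, MADE2 and MADE1, at 0 in all 6 oocytes, were at least 33.9-fold, 20.7-fold and 16.3-fold higher in the 4 zygotes. Of 280 ERV1 subfamilies 122 fell and 6 rose (132 by list alone), and of 30 ERVK subfamilies 17 fell (18 by list alone), with adjusted p = 4.45e-20 and 1.94e-08, or 0.135 and 0.0413 with an estimated correlation. The step had 2790 genes up and 1055 down of 14601 (3845, but 619 with the replicate factor and 2358 with the strict filter) and 42 repeats up and 383 down of 1123, or 97 genes up and 2992 down with 7 repeats up and 608 down under spike-in scaling (median −1.92). From zygote to 2-cell embryo (2 embryos) LTR23 rose by 4.44 ± 0.486, ALR by 5.53 ± 0.971 and MER50C by 5.10 ± 0.885. UCON97 fell by 11.35 ± 1.54, and D20S16 and MADE2, at 0 in both 2-cell embryos, were at least 73.7-fold and 45-fold lower. ERV1 subfamilies rose in 17 of 280 cases (131 by list alone, adjusted p = 5.66e-56, or 0.00279 with an estimated correlation). Only 9 genes rose and 25 fell, with 55 repeats up and 6 down, and spike-in scaling (median 0.68) gave 15 genes up and 3 down, with 4 repeats up and 1 down. Leaving out 1 library moved the 34 genes to between 4 (without 2-cell replicate 1) and 73 (without zygote replicate 1), with 17 and 20 without zygotes 2 and 3 and 14 without 2-cell replicate 2.

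Between the rhesus 2-cell and 8-cell stages (2 and 3 embryos) ENSMMUG00000048019, at 0 in both 2-cell embryos, was at 27.7 ± 13.7 CPM, at least 37.5-fold higher, and ENSMMUG00000005986 rose by 7.45 ± 1.08. All 3 8-cell embryos had gene profiles nearer to another stage. HERVK rose by 4.44 ± 0.7 to 1405 ± 1258 CPM (adjusted p = 0.013) and LTR5B, its LTR, by 2.77 ± 0.5 (adjusted p = 0.0385). By edgeR 6 genes rose and 0 fell (1575 at an unadjusted p under 0.05), by DESeq2 214 passed, and under spike-in scaling (median −1.27) 0 rose and 0 fell. HERVK and LTR5B did not pass either under that scaling, at 4.1 and 2.07 here and at 4.49 and 3.78 at the next step. The 6 became 0 without either 2-cell embryo and 13 without 8-cell replicate 3, which had 38.8% of its counts in spike-ins. Alu subfamilies, 0 of 32 past the test but 26 by list alone, had a median of 1.54 that became −0.38 under spike-in scaling (adjusted p = 5.16e-16, or 0.159 with an estimated correlation). From the 8-cell to the 16-cell stage HERVK rose by 4.404 ± 0.585 to 29760 ± 13030 CPM, LTR5B by 3.36 ± 0.436 and MER68B by 3.11 ± 0.775. LTR47B fell by 6.91 ± 1.82, UCON9 by 4.37 ± 1 and LTR1B0 by 4.20 ± 0.804, and UCON17, at 0 in all 3 16-cell embryos, was at least 12.9-fold lower. ERVL subfamilies fell in 59 of 123 cases and rose in 1 (70 by list alone, adjusted p = 3.34e-17, or 0.161 with an estimated correlation). There were 1976 genes up and 1761 down (3737, but 1801 without 16-cell replicate 3, 1572 with the replicate factor and 449 with 2 groups only), 13 repeats up and 324 down, and with spike-in scaling (median 0.69) 41 genes up and 2 down, with 0 repeats up and 0 down. From oocyte to 16-cell embryo HERVK rose by 8.88 ± 0.521, LTR5B by 6.59 ± 0.374, MER11A by 6.11 ± 0.372 and LTR14C by 5.41 ± 0.933, with HERVK and LTR5B past the test under spike-in scaling too (7.2 and 4.81). LTR47B2 fell by 5.48 ± 0.684, LTR38C by 5.22 ± 0.601, LTR1C by 5.17 ± 0.78 and LTR22A by 4.71 ± 0.654. Of 32 Alu subfamilies 26 rose (26 by list alone), a median of 1.59 that became −0.14 under spike-in scaling (adjusted p = 3.51e-07, or 0.972 with an estimated correlation). Over that span 3331 genes rose and 2855 fell, with 366 repeats up and 211 down, and spike-in scaling (median −1.67) gave 565 genes up and 2599 down, with 10 repeats up and 149 down.

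From oocyte to 16-cell stage (day 3 in pig), shares of some repeat subfamilies moved together across the 5 species. Of 200 subfamilies tested in all 5, 25 rose and 13 fell in every species, where shuffled names gave means of 2.46 and 0.324 and at most 9 and 4 (permutation p = 1e-04 for each, the smallest 10000 shufflings can give). The ERVL element LTR52 fell in mouse, pig, cow, rabbit and rhesus by 3.20, 1.60, 3.91, 2.33 and 2.87, and MLT2F, MLT1D, MLT1E1A, MER5B and MER5A also fell in each. Most of those that rose were L1 segments, among them L1M2_orf2, L1MC4_5end, L1MB4_3end, L1MA10_3end and L1M4c_5end, which reversed in pig under spike-in scaling (−0.19, −0.34, −0.53, −0.22 and −0.395), as L1MC4_5end did in cow (−1.31). Under that scaling, run after the data were seen, 0 rose and 26 fell in every species (17.2 by shuffling, permutation p = 1 and 5e-04), and 0 of 10 tests of a pair of species passed for risers and 2 of 10 for fallers. With a change of at least 2-fold in each species 13 rose and 4 fell in every one. Without it all 20 tests of a pair in one direction passed, from 88 shared risers of pig and cow against 51.5 expected (one-sided Fisher's exact test, adjusted p = 6.8e-14) to 29 shared fallers of mouse and pig against 18.8 (adjusted p = 0.000667). These tests, chosen once gene identifiers of 4 species proved unnamed, treat subfamilies as independent, so L1 segments moving together could lower p.

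Late 2-cell mouse embryos processed with the parent protocol and with the added polyadenylation step (2 libraries each) had few genes past the test, in groups too small to find most changes. The added step had 54 genes higher and 189 lower of 18289 tested (2044 at an unadjusted p under 0.05, and 948 by DESeq2), but the 56299 entries of this table carry no identifiers and match in number the genes, repeats and spike-ins of the mouse table together, so repeats and spike-ins could not be set apart. Leaving out 1 library at a time gave between 144 (without replicate 8 of the added step) and 478 genes (without replicate 5 of the parent protocol), with 414 without replicate 7 of the added step.

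Mouse embryonic stem cells, compared with 16-cell embryos, had more glycolysis messages and fewer genome activation messages. Stmn2 (ENSMUSG00000027500.10, chromosome 3, 8509360 to 8561606), a microtubule-binding stathmin, rose by 10.75 ± 0.372, the tubulin gene Tubb2b by 9.93 ± 0.35, the endocytic receptor gene Ly75 by 9.47 ± 0.364, Platr3 by 9.21 ± 0.387 and Ftl2-ps by 11.31 ± 0.618. Trh, at 0 in all 12 16-cell embryos, was at 51.4 ± 16.8 CPM in the 6 stem cell libraries, at least 11.9-fold higher. Timd2 (ENSMUSG00000040413.15, chromosome 11, 46668960 to 46707061), at 2196 ± 394.1 CPM in embryos, was at 0 in all 6, at least 1030-fold lower, and Pramel4, Pramel5, Gata6, Slc34a2, Fcgr3 and Parp8 were at least 147-fold, 127-fold, 116-fold, 101-fold, 64.1-fold and 60.3-fold lower. The phosphatase gene Alppl2 changed by −13.70 ± 0.442 and Trim43a by −11.81 ± 0.459. Glycolysis genes rose in 15 of 17 cases and fell in 1 (17 by list alone), Pfkp by 6.70 ± 0.322, Ldha by 6.42 ± 0.312 and Gapdh by 6.23 ± 0.281. Hk1 changed by −1.36 ± 0.249 (adjusted p = 6.34e-07, or 0.00771 with an estimated correlation). Genome activation markers fell in 14 of 16 cases and rose in 1 (15 by list alone), Trim43b by −8.73 ± 0.363, with a median of −7.05, or −5.74 with the 2 members at 0 set to their bound (adjusted p = 1.93e-07, or 0.029 with an estimated correlation). Pluripotency factors divided, 12 of 22 rising and 6 falling (18 by list alone, adjusted p = 0.284), with Sox2 at 4.23 ± 0.5, Nanog at 3.62 ± 0.397, Dppa2 at −3.20 ± 0.254 and Nr5a2 at −2.998 ± 0.258. All 3 fibroblast markers tested rose, Acta2 by 6.05 ± 0.449, Col1a1 by 5.90 ± 0.446 and Col1a2 by 3.51 ± 0.534. Mitochondrially encoded messages fell in 12 of 13 cases (12 by list alone, adjusted p = 0.000132, or 0.499 with an estimated correlation). The LTR ERVB7_1-LTR_MM rose by 4.67 ± 0.265, L1MdA_I_5end by 3.37 ± 0.278 and ETnERV by 3.33 ± 0.216. MT2C_Mm fell by 5.36 ± 0.32, MT2B by 5.08 ± 0.257 and RLTR45-int by 4.67 ± 0.348. There were 3805 genes up and 3264 down of 10428, and 59 repeats up and 391 down of 715. Stem cells and embryos came in separate tables without shared spike-ins, so the cell type and the batch cannot be told apart.

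Rabbit embryonic stem cells, summed to 3 samples by culture number, had fewer MLT1H LTR counts than morulae. MLT1H went from 24410 ± 25510 to 118.3 ± 32.5 CPM (−7.69 ± 1.41), 7SLRNA changed by −4.32 ± 0.855, U1 by −3.92 ± 0.621, MLT1H2 by −3.44 ± 1.09, LTR79 by −3.02 ± 0.335 and FordPrefect by −4.69 ± 1.42. UCON4 rose by 4.43 ± 0.576, MER58C by 3.33 ± 0.205, MER65D by 3.14 ± 0.343, X9b_DNA by 3.12 ± 0.466 and MER83B-int by 2.03 ± 0.221. hAT-Charlie subfamilies rose in 32 of 65 cases and none fell (31 by list alone, adjusted p = 0.000248, or 0.603 with an estimated correlation), and TcMar-Tigger subfamilies in 18 of 27 and none fell (20 by list alone, adjusted p = 0.000577, or 0.603 with an estimated correlation). In all 2146 genes rose and 2521 fell of 8137, with 150 repeats up and 30 down of 479, and here too the cell type and the batch cannot be told apart.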

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

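The tests of spike-in scaling, of repeat background and of stage labels in this part were chosen only after the results were seen, while those of transcript length, pseudogenes and sequencing depth were written beforehand.

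Mouse ribosomal protein messages were lower in zygotes than in oocytes. Shorter transcripts might be lost more easily. The 2847 protein-coding genes matched at 634.5 to 2632 bases had a median of −0.43, 2.4 above the list (SD 1.51). So wide a window leaves length open. Reads might be shared with pseudogenes, yet the sum of the list and all annotated pseudogenes still changed by −1.3 (SE 0.087), the list falling from 24580 to 5091 CPM while pseudogenes stood at 8234 and 8190 CPM. Other features could have taken a larger share of the counts, but under spike-in scaling the list median was −4.36 (SD 1.52). Loss of the poly(A) tail rather than of the message remains possible and was not tested.

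Repeat subfamilies were lower in pig, cow and rhesus zygotes than in oocytes. Loss of intronic or genomic background would lower all repeat classes alike. By median, LTR subfamilies differed from the old MIR and L2 repeats by −0.0124 in pig (SD 0.557), −0.018 in cow (SD 0.188) and 0.208 in rhesus (SD 1.12). By counts, the log2 ratio of LTR to MIR and L2 changed by −0.029 in pig (SD 0.108) and −0.115 in cow (SD 0.148), within the spread, so a loss of background and decay of repeat transcripts both stay open there. In rhesus it changed by −1.12 (SD 0.538), every zygote (0.46 to 1.76) lying below every oocyte (2.12 to 2.43), which argues against an equal loss from all classes as the whole cause. The rhesus median, with its wide SD, decides nothing, and an unequal loss of background stays open.

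Some embryos had genes that matched another stage. Rabbit 2-cell replicates 9 and 12 both (2 of 2) lay within the range of 4-cell libraries (0.8898 to 0.9779) with r of 0.9559 and 0.9477, against 0.9095 and 0.8992 with their own stage. That range also holds 2-cell replicates 2 and 10 (0.9276 and 0.9134), so it does not separate the stages, and whether the label is wrong stays open. Pig day-3 replicate 1 is less likely a mislabelled 4-cell embryo, its r of 0.8863 lying 0.054 below the lowest 4-cell library (a difference of −0.054, 0.9403 for that library), and an arrested embryo was not tested for. Low sequencing depth is not a likely reason, since 0 of 19 other libraries came nearer another stage when thinned to the lowest total.

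Single libraries stood apart by Dixon's test in 4 of 26 groups of 4 to 10 libraries by measure, where about 1 in 20 would by chance. Mouse stem cell replicate 4 had a total count of 7385000, and rabbit stem cell library R2T1 one of 4662000. Mouse stem cell replicate 2 had a repeat share of 13.21%. Late 2-cell mouse replicate 10 had a log2 ratio of endogenous to spike-in counts of 3.099.

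The single rhesus 4-cell library entered no comparison. It had 1325.3 CPM of HERVK (95% Wilson interval 1292 to 1359.4), 3486.3 of LTR5B (3432.1 to 3541.3) and 17231 of AluY (17111 to 17352).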

How the results depend on the processing

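Spike-in scaling, leaving out libraries rich in spike-ins, genes without repeats, the 5 rabbit stem cell libraries unsummed, repeat subfamilies in place of genes and leaving out libraries nearer another stage were chosen only after the results were seen, and the other settings before.

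Spike-in counts varied widely between libraries, the rhesus and parent protocol groups were small, and replicate numbers did not pair libraries across stages (mean r of same-number libraries between −0.0953 and 0.145). Of 343 counts of genes under another setting 257 kept within a ratio of 1.5 and 86 moved, as did 62 of 300 counts of repeats. Of 4107 values for named genes and repeats 3955 stayed, 126 were weaker and 26 reversed, and of 181 gene list tests 61 passed, of which 54 were lost and 7 kept with an estimated correlation. Of 569 repeat family tests 182 passed and 19 were kept. DESeq2 size factors in edgeR moved none of the 36 gene counts. No library was shallow enough to leave out, and the setting with 10 rabbit stem cell libraries was replaced by the 5 with counts. The cause of the moves below was not tested, apart from the numbers tested, which a filter sets by construction.

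Without a filter, genes called went from 7839 to 14931 for early to late 2-cell in mouse, 5621 to 10430 for late 2-cell to 4-cell, 4568 to 8127 for 4-cell to 8-cell, 1246 to 1994 for 8-cell to 16-cell and 10064 to 20964 for oocyte to 16-cell. In pig they went from 9 to 102 for 2-cell to 4-cell, 5946 to 9256 for day 2 to day 3, 4220 to 6897 for day 3 to morula and 5947 to 10481 for oocyte to day 3. In cow they went from 88 to 162 for 4-cell to 8-cell, 6371 to 11664 for 16-cell to morula and 8327 to 13584 for oocyte to 16-cell. In rabbit they went from 1316 to 2121 for 2-cell to 4-cell, 5621 to 9019 for 4-cell to 8-cell, 2886 to 4569 for 16-cell to morula and 6806 to 11708 for oocyte to 16-cell. The added polyadenylation step went from 243 to 375 and mouse stem cells from 7069 to 12599.

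DESeq2 called 12070, 8880, 7178 and 1974 genes at the 4 mouse steps from early 2-cell to 16-cell and 16757 over the span. It called 131 in pig from 2-cell to 4-cell, 6699 from day 3 to morula and 9332 from oocyte to day 3. In cow it called 266 from zygote to 2-cell in place of 124, 229 from 4-cell to 8-cell and 10355 from 16-cell to morula, and in rabbit 2461 from 2-cell to 4-cell and 4666 from 16-cell to morula. In rhesus it called 290 from zygote to 2-cell in place of 34 (15 up and 275 down) and 214 from 2-cell to 8-cell in place of 6 (185 up and 29 down), and 948 for the added polyadenylation step. With all stages in 1 fit the counts were 9057 from late 2-cell to 4-cell and 7405 from 4-cell to 8-cell in mouse, 457 from zygote to 2-cell in place of 736 and 98 from 2-cell to 4-cell in pig, 555 from 2-cell to 4-cell in place of 981, 185 from 4-cell to 8-cell and 9907 from 16-cell to morula in cow, and 4686 from 16-cell to morula in rabbit. Splits shifted there too, to 3556 up and 6351 down from cow 16-cell to morula and 1811 up and 2875 down from rabbit 16-cell to morula.

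The strict filter left 2 genes from pig 2-cell to 4-cell, and in rhesus 2358 from oocyte to zygote in place of 3845, 68 from zygote to 2-cell, 2041 from 8-cell to 16-cell and 4091 from oocyte to 16-cell, with 487 for the added polyadenylation step. The replicate number as a factor gave 2 from pig 2-cell to 4-cell, 23 from cow zygote to 2-cell, and in rhesus 619, 2, 0 and 1572 over the 4 steps and 3437 from oocyte to 16-cell. Fitting 2 rhesus groups only gave 0 from zygote to 2-cell, 0 from 2-cell to 8-cell and 449 from 8-cell to 16-cell (309 up and 140 down). Without libraries rich in spike-ins rhesus gave 94 from zygote to 2-cell and 13 from 2-cell to 8-cell, and genes without repeats gave 10 from zygote to 2-cell. Leaving out 1 library gave 4 to 73 genes from rhesus zygote to 2-cell, 0 to 13 from 2-cell to 8-cell, 1801 to 4610 from 8-cell to 16-cell (1801 without 16-cell replicate 3 and 2194 without replicate 1) and 144 to 478 for the added polyadenylation step.

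Spike-in scaling gave 115 genes from mouse 8-cell to 16-cell and 1 from pig 2-cell to 4-cell. In cow it gave 9818 from oocyte to zygote in place of 3861, 66 from zygote to 2-cell, 112 from 2-cell to 4-cell and 503 from 4-cell to 8-cell, and in rabbit 936 from zygote to 2-cell in place of 2156 and 219 from 2-cell to 4-cell. In rhesus it gave 18 from zygote to 2-cell, 0 from 2-cell to 8-cell, 43 from 8-cell to 16-cell in place of 3737 and 3164 from oocyte to 16-cell in place of 6186. It reversed 26 repeats. In pig MamGypLTR1a went to −0.262 from oocyte to zygote and MLT1C to −0.0177 from zygote to 2-cell. From pig 4-cell to day 2 MLT1E3 went to −0.134, L1MB5_3end −0.0439, MER58B −0.11, L2a_3end −0.249, MLT2C1 −0.274, L1ME3F_3end −0.293, LTR33A_v −0.568 and MamRTE1 −0.491. From pig oocyte to day 3 L1M2_orf2 went to −0.191, L1MA10_3end −0.223, tRNA-Arg-CGA −0.219, L1MC4_5end −0.342, tRNA-Ile-ATT −0.376, L1MB4_3end −0.527, L1M4c_5end −0.395, GirTip-1.94 −0.76 and LSU-rRNA_Hsa −0.615. From cow oocyte to 16-cell MER104 went to −0.355, MamRTE2 −0.824, MER70-int −0.894, MLT2B4 −1.28, L1MC4_5end −1.31 and Charlie1a −1.29, and from rabbit 16-cell to morula MLT2F went to 0.23.

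With at least 2-fold changes required, repeat subfamilies that rose in all 5 species went from 25 to 13 and those that fell from 13 to 4. Spike-in scaling gave 0 that rose and 26 that fell. Of 88 overlaps under another setting 33 moved, among them 18 of 22 under that scaling and 13 of 22 at 2-fold.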

Other observations

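The splits of repeat counts in this part were chosen only after the results were seen, and the splits of gene counts before.

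Single genes followed distinct courses in mouse, here in plain CPM. Gdf9, an oocyte growth factor, was at 4261 ± 755 CPM in oocytes, 1326 in zygotes, 392.7 in early and 95.9 in late 2-cell embryos and 3.99 ± 1.71 at the 16-cell stage, and Mos went from 696 ± 153 to 43.1 in zygotes. Pou5f1 dropped from 224.4 CPM in early to 42.5 in late 2-cell embryos, then stood at 36.1, 341.2 and 450.9 ± 78.6 at the 4-cell, 8-cell and 16-cell stages. Gata6 went from 8.22 at the 4-cell stage to 132.6 ± 65.2 and 248.5 ± 129 CPM. Dppa3, a factor that protects maternal methylation, held 2153 CPM or more in every embryo stage and stood at 27.8 in stem cells. Klf17 was highest in early 2-cell embryos at 897.8 CPM.

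Repeat levels peaked at different stages. The mouse LTR MTA_Mm stood at 60050 CPM in oocytes, 32940 in zygotes, 88440 in early 2-cell embryos and 429 at the 16-cell stage, and MERVL at 19360 ± 7590 in late 2-cell embryos and 501 at the 16-cell stage. In pig tRNA-Arg-CGY, classed as a tRNA pseudogene and not as a retrotransposon, stood at 266300 ± 59650 CPM in morulae. On day 3 it stood at 104400 ± 88860 (single embryos 24080 to 303800). In cow BosInd-1.230 went from 133.3 ± 38.6 CPM at the 8-cell stage to 5487 ± 2301 and then 2904 ± 1161 in morulae. In rabbit MLT1H stood at 78050 ± 22120 CPM at the 8-cell stage and 91 in stem cells.

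Random splits asked whether the counts called could arise without the stage difference. For each comparison of groups of at least 3 libraries, save 1 given below, 25 splits into groups of the same sizes were drawn at random, and the real split made 26. In mouse the real split had 6556, 2933, 7839, 5621, 4568 and 1246 genes over the 6 steps and 10064 over the span, and the largest drawn split 237, 20, 0, 2001, 0, 57 and 0. In pig it had 4824, 736, 9, 1671, 5946 and 4220 genes and 5947 over the span, against 0, 0, 1, 373, 0, 312 and 0. In cow it had 3861, 124, 981, 88, 8637 and 6371 genes and 8327 over the span, against 1, 30, 276, 0, 0, 0 and 939. In rabbit it had 6066, 2156, 1316, 5621, 2755 and 2886 genes and 6806 over the span, against 2005, 510, 0, 2423, 0, 0 and 0. Rhesus oocyte to zygote had 3845 against 31 and oocyte to 16-cell 6186 against 0, mouse stem cells 7069 against 0, and rabbit stem cells 4667 against 1. In each of these 1 of 26 splits, the real one, reached the real count. For rhesus 8-cell to 16-cell, 3737 against 1007, only 10 splits exist, which is too few to weigh a value of 1. Splits were not run for rhesus zygote to 2-cell and 2-cell to 8-cell or for the added polyadenylation step, where a group has 2 libraries.

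For repeats the real split was again the only one of 26 (a value of 1) in every comparison so split except cow 2-cell to 4-cell, with pig 2-cell to 4-cell calling 0 and rhesus 8-cell to 16-cell having only 10 splits. In mouse it called 203, 326, 503, 174, 124, 58 and 595 over the 6 steps and the span, against at most 13, 41, 0, 47, 0, 1 and 0. In pig the counts were 256, 8, 96, 259, 184 and 329 (none at 2-cell to 4-cell) against 0, 0, 3, 0, 5 and 0, and in cow 153, 3, 1, 324, 135 and 324 against 0, 0, 0, 0, 0 and 41. From cow 2-cell to 4-cell 2 of 26 splits did as well, with 7 repeats in a drawn split and 6 in the real one, so those 6 are not to be relied on. In rabbit the counts were 272, 118, 61, 244, 89, 194 and 321 against 102, 104, 1, 73, 0, 0 and 0. They were 425 against 0 and 577 against 0 in rhesus oocyte to zygote and to 16-cell, 337 against 42 among the 10 splits of rhesus 8-cell to 16-cell, 450 against 0 in mouse stem cells and 180 against 0 in rabbit stem cells.

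Rhesus 8-cell embryos and zygotes 1 and 4 were nearer another stage than their own. The 8-cell replicates 1 and 2 were nearest the 2-cell stage (r = 0.8699 and 0.8951, against 0.7552 and 0.5859 with the other 8-cell embryos), and replicate 3 had r = 0.3463 with them. Zygote replicate 1 had r = 0.3712 with the other zygotes and 0.7983 with the 4-cell embryo, and replicate 4 had 0.8098 and 0.8707 with 2-cell embryos. Zygotes 2 and 3 had 0.9258 and 0.9061, and 0.9239 each with 2-cell embryos, both 2-cell embryos 0.9343, and 16-cell embryos 0.9128 to 0.9467. Leaving out such libraries was not run in rhesus, but leaving out 1 zygote gave 3033 to 4337 genes from oocyte to zygote (4337 without replicate 1 and 3103 without replicate 4). Rhesus oocytes had r of 0.9673 to 0.9794 with the mean of the others.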
